A study of Arabidopsis thaliana with 8 samples.

How the data were processed

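RNA of whole dark-grown Arabidopsis thaliana seedlings was compared on 8 arrays with 2 dyes each. Per the labels, seeds were stratified for 4 days, given 8 h of white light and kept in darkness, and seedlings were 7 days old. Paclobutrazol (PAC) inhibits gibberellin (GA) synthesis, epibrassinolide (EBR) is an active brassinosteroid (BR), GA3 is an active gibberellin, and det2-1 is a mutant in the BR synthesis gene DET2. In the first experiment PAC seedlings were set against mock-treated seedlings and against seedlings given PAC and EBR. In the second, det2-1 was set against wild type (WT) and against det2-1 given GA3. Each experiment had 4 arrays from 2 biological repeats, so each comparison rests on 2 arrays. Treatment doses are not printed because their units in the labels are doubtful.

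Per the file headers, slides were scanned with a GenePix 4000B scanner and quantified with GenePix Pro version 6.0.0.76. The scanner files hold a foreground and a local background intensity per spot and dye, per the file headers, with no normalization. The authors also deposited a table of log2 ratios. Set against the scanner values, its columns had slopes of 1.00 or -1.00 with the log2 ratio of background-subtracted medians, so its scale was settled. A slope does not show whether the ratios of an array were centred. Column medians ran from -0.041 to 0.048. Its columns run as mock over PAC, PAC+EBR over PAC, det2-1 over WT and det2-1 over det2-1 with GA3, and 44.8 to 55.2% of spots per array have no value there. The only flag in the scanner files marks spots the software did not find, 38.3 to 49.9% of gene spots per array, and 10923 genes were found on all 8 arrays. These dim spots were kept. No outlier flag occurred, so the alternative that keeps such spots was not run.

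Each array has 28800 spots, of which 25424 carry a gene's locus code. The other 3376 are control or unnamed spots and were left out of the tests. Backgrounds were corrected with normexp and an offset of 50, ratios were normalized within each array by loess with control spots at weight 0, and spots of a probe were averaged. A gene took the value of its probe with the highest mean brightness. This gave 24063 genes from 25232 probes, 1119 of them with several probes. Passing probes of a gene went in opposite directions for 0 genes with PAC, 1 with EBR, 5 in det2-1 and 0 with GA3. Symbols came from the gene lists and from a RefSeq gene table of assembly TAIR10.1, which matched 23690 genes. The build behind the array's annotation is not given in the sources used here, so no coordinates are printed. Median foreground intensity ran from 127 to 258 in Cy5 and from 213 to 388 in Cy3, and the number of arrays limits the precision.

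Log2 ratios were tested with limma 3.58.1 in R (lmFit and eBayes). A single fit of the 8 arrays held 4 effects and a dye effect per gene, with 3 residual and 4.42 prior degrees of freedom. PAC samples were always in Cy3, so their dye bias is taken from the dye swap of the second experiment and assumed equal in both. The dye effect passed for 258 genes. It correlated with the mean ratio of the first experiment at 0.27 over all genes and 0.10 over brighter ones. Calls have a Benjamini-Hochberg adjusted p under 0.05 over all genes, and an error given as SE is the fit's own. A gene not above background (at least 50% of pixels above background in any of its probes) in either array of a group has only a bound, "at least N-fold", and a gene not above background in both groups has no value printed. The bound is computed per channel after loess and Aquantile and open to dye bias in the first experiment. In it a dim signal is raised to the lowest signal of any gene above background in that channel. That floor is low, so "at least" is approximate and not a guaranteed minimum, and some bounds equal the fitted fold. For PRE1 and COBL4 with PAC the bound exceeded the fitted fold, so the fitted fold is given.

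A set of 22 gene lists with 254 genes, 11 of them without a probe, was fixed before the data were examined. So was the rule for named genes. For each main comparison it takes the 5 largest rises and 5 largest falls among called genes with the same sign in both arrays and brightness above the median, up to 3 called members of each list by size of change, and always DET2, CPD, DWF4, BR6OX2, GA20OX1, GA20OX2, GA3OX1 and GA2OX1. For each of 4 derived tests it takes the 3 highest and 3 lowest and the called genes among those 8. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 88 list and comparison pairs, with camera's estimated correlation and fry beside it. No list call held with the estimated correlation. That variant also rests on the 3 residual degrees of freedom, so a lost call does not by itself show correlation between genes. For chlorophyll synthesis with PAC the estimated correlation was -0.037, below the preset, yet the unadjusted camera p went from 1.08e-08 to 0.0094. Seed storage genes had an estimated correlation of 0.84.

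The labels number the repeats, and the series text describes 2 repeats of 3 samples each, so arrays of the same number were taken to share the PAC or det2-1 sample. The labels imply but do not state that a single extract was used on both, and the simulations assume it. Deviations of same-numbered arrays correlated at 0.60 in the first experiment and 0.67 in the second, across genes. Over brighter genes the values were 0.67 and 0.49. A shared sample gives a positive correlation by itself. In the second experiment dye bias also enters both deviations with the same sign, so the size of these values does not settle the sharing. A fit with the replicate number as a block, set in the first experiment only, was run beside the main design. In the second experiment the replicate number runs with dye orientation and is taken up by the dye effect. Values of the second experiment under this block therefore change only through the shared estimate of the spread. The scripts were tested on simulated data of 24063 genes. With changes planted in the GA3 comparison in a single draw, and noise independent between arrays, 100% of changes of log2 size 1 and 37.0% of size 0.5 were recovered. For the PAC effect the shares were 95.7% and 7.46%. With noise independent between arrays, 5.16% of calls for the PAC effect were false. With all noise in the samples that arrays share, false calls made up 11.8% for the PAC effect, 12.0% for the EBR effect, 8.30% for the det2 effect and 7.78% for the GA3 effect. In those simulations the replicate block gave 35.5% false calls for the PAC effect, 36.7% for the EBR effect, 27.4% for the det2 effect and 26.5% for the GA3 effect. Scan day as a random block gave 56.9% for the det2 effect and 73.3% for the GA3 effect, but 7.89% for the PAC effect and 7.15% for the EBR effect, below the main design. Counts under these blocks are given beside the main counts but not led with.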

Results

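Transcript levels were compared on 8 two-dye arrays of etiolated Arabidopsis seedlings, 2 per comparison. The first experiment asked how PAC, which inhibits GA synthesis, and EBR added to it, changed transcripts of wild-type seedlings. The second asked the same of BR deficiency in det2-1 and of GA3 added to it. The arrays measured 24063 genes. Ratios of the 2 PAC arrays correlated at 0.73 across genes (0.78 over brighter ones), those of the EBR arrays at 0.67 (0.71), those of the det2 arrays at 0.71 (0.85) and those of the GA3 arrays at -0.35 (-0.03). The PAC and EBR pairs share dye orientation while the det2 and GA3 pairs are dye swaps, so these values are not alike. Genes are not independent replicates.

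PAC raised transcripts of chlorophyll synthesis, photosynthesis and seed storage. PORA and PORB, which reduce protochlorophyllide, were higher than in mock seedlings by a log2 change of 2.45 (SE 0.25, n = 2 arrays, limma adjusted p = 0.0044) and 2.17 (SE 0.18, adjusted p = 0.0029). Among GA synthesis genes, GA20OX2 rose by 2.24 (SE 0.36, adjusted p = 0.014) and KAO2 by 0.82 (SE 0.14, adjusted p = 0.016). In all, 1434 genes were higher and 861 lower with PAC.

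Chlorophyll synthesis genes rose together with PAC, with 8 of 10 measured members higher, 0 lower and 2 not passing, and 8 higher when adjusted over the list alone. CHLH, a magnesium chelatase subunit, had a log2 change of 1.77. The list's medians were 1.41 and 1.07 in the 2 arrays (camera adjusted p = 1.58e-07, adjusted p = 0.30 with an estimated correlation). Of 24 photosynthesis genes 13 rose, 0 fell and 11 did not pass, and 20 rose when adjusted over the list alone. Examples were PSAK of photosystem I at 1.90, LHCB2.1 at 1.33 (0.07 in a dim second probe) and RBCS1A at 1.33. Their median was 0.85 (camera adjusted p = 2.63e-12, adjusted p = 0.48 with an estimated correlation). Light signalling genes had 6 of 15 members higher, among them ELIP1 at 1.13, PIL1 at 1.11 and ELIP2 at 0.85 (camera adjusted p = 0.0029, adjusted p = 0.31 with an estimated correlation).

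Seed storage transcripts rose with PAC in 11 of 11 measured genes, also 11 when adjusted over the list alone, in the same arrays in which photosynthesis and chlorophyll genes rose. EM6, a late embryogenesis protein, rose by 2.98, and the cruciferins CRC and CRA1 by 2.84 and 2.52. The median was 1.90 (camera adjusted p = 1.34e-10, adjusted p = 0.48 with an estimated correlation), at 2.39 in the array of repeat 1 and 1.44 in that of repeat 2. The 5 largest rises by the naming rule were HSD1, an oil body steroid dehydrogenase, at 3.95 (SE 0.40), AT1G68250 at 3.61, AT3G01570 at 3.11, GASA3 at 8.56-fold and EM6. Second probes gave 2.11 for CRC, 3.47 for CRA1, 2.36 for HSD1 and, for a dim one, 0.36 for AT1G68250.

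GA3OX1 did not pass with PAC, at a log2 change of 1.03 (SE 0.30, adjusted p = 0.078, 0.0067 with the replicate block), and GA20OX1 was not above background in PAC or mock seedlings on these arrays. GA2OX1 stood at -0.26 (adjusted p = 0.25). The second, dimmer probe of GA20OX2 gave 1.01. The GA synthesis list had 2 of 11 members higher and 0 lower, and 4 higher when adjusted over the list alone (camera adjusted p = 0.21, 0.034 without the mock array of repeat 2). SCL3, a GRAS protein of the GA pathway, rose by 0.49. The BR synthesis list had 0 of 10 members passing, 1 when adjusted over the list alone (camera adjusted p = 0.88). CPD stood at -0.05 (SE 0.13), DWF4 at 0.03 (SE 0.26), DET2 at -0.11 (SE 0.15) and BR6OX2 at 0.46 (SE 0.19, adjusted p = 0.18, 0.032 with the replicate block).

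Wall and auxin genes moved both ways with PAC. In the XTH family of wall enzymes 4 of 15 members rose and 4 fell, 6 and 5 when adjusted over the list alone, with XTH25 at 1.86, XTH15 at 1.64 and XTH17 at -1.21 (camera adjusted p = 0.88). EXPA11, an expansin, rose by 0.84. The auxin repressor gene IAA19 had a log2 change of -1.01 and IAA14 of -0.69, while GH3.3 stood at 1.00, in a list with a median of -0.22 (camera adjusted p = 0.043, adjusted p = 0.69 with an estimated correlation). That list call was lost without the mock array of repeat 1 (adjusted p = 0.35) or either GA3 array (0.26 and 0.25). The second probe of IAA19 gave -0.54. Among BR-induced genes EXO rose 2.63-fold. PRE1 was 2.48-fold lower in the fit, being not above background in PAC seedlings. BZR1, a BR transcription factor, had a log2 change of -0.73, ACS11 of -0.83, the cytokinesis gene KNOLLE of -0.53 and ACT8 of -0.53. COBL4, not above background in PAC seedlings, was 1.52-fold lower in the fit. The secondary wall list had 1 of 10 members lower, 7 when adjusted over the list alone, with a median of -0.53 (camera adjusted p = 2.24e-04, adjusted p = 0.54 with an estimated correlation). Flavonoid genes CHS and CHI rose by 1.52 and 0.77, in a list with 2 of 12 members above background in PAC seedlings that did not pass (camera adjusted p = 0.17, 0.040 without the mock array of repeat 2), and PAP1 was not above background in either group. The largest falls were AT1G55240 at -1.87, AT2G17500 at -1.81, CYP82C2 at -1.79, AT5G52710 at -1.79 and AT4G20320 at -1.74.

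Where an array of the second experiment is left out, its remaining arrays are fitted exactly. The spread then comes from the first experiment alone, which can change call counts of every effect. The PAC count was 6229 with the replicate block, 1627 with scan day as a random block, 117 with plain background subtraction (88.0% higher against 62.5% here), 1832 with median centring (52.7%), 571 at an absolute log2 change of at least 1 (80.2%) and 1466 with the deposited values (47.5%). It was 186 without the mock array of repeat 1 (87.6% higher), 1403 without that of repeat 2, 158 without either det2-1 against WT array (91.8%) and 124 without either GA3 array (87.9%).

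The BR synthesis genes BR6OX2, CPD and DWF4 fell with EBR. Relative to PAC alone, BR6OX2 had a log2 change of -1.96 (SE 0.19, adjusted p = 0.0037), CPD of -1.39 (SE 0.13, adjusted p = 0.0031) and DWF4 of -1.38 (SE 0.26, adjusted p = 0.019), each lower in 2 of 2 arrays. The BR synthesis list had 4 of 10 members lower, 1 higher and 5 not passing, with the same counts when adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.057, 0.016 without the EBR array of repeat 2, 0.048 without the det2-1 against WT array of repeat 2). DET2 stood at 0.08 (SE 0.15). EARLI1 and LTP3, lipid transfer protein genes, rose by 3.77 (SE 0.25) and 3.36 (SE 0.38). In all, 1208 genes were higher and 1280 lower.

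Photosynthesis genes fell with EBR in 12 of 24 members, 15 when adjusted over the list alone, with PSAK at -1.57, LHCB2.1 at -1.39 (-0.15 in the dim second probe) and PSAF at -1.28 (median -0.76, camera adjusted p = 1.72e-09, adjusted p = 0.48 with an estimated correlation). Chlorophyll synthesis genes fell in 8 of 10, also 8 when adjusted over the list alone, with PORA at -1.14, CHLH at -1.09 and GUN4 at -0.95 (camera adjusted p = 1.74e-05, adjusted p = 0.30 with an estimated correlation). Seed storage genes fell in 4 of 11, 7 when adjusted over the list alone, including AT2S1 at -1.76, AT2S4 at -1.50 and AT2S2 at -1.36 (camera adjusted p = 3.21e-05, adjusted p = 0.61 with an estimated correlation). Of 6 root hair genes, 3 above background with EBR, 3 fell, 4 when adjusted over the list alone. These were PRP3 at -1.83, EXPA18 at -1.57 and EXPA7, which was not above background in either group (camera adjusted p = 3.10e-04, adjusted p = 0.48 with an estimated correlation).

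Primary wall cellulose genes rose with EBR in 4 of 8 members, 5 when adjusted over the list alone. COB rose by 0.96, CESA1 by 0.74 and KOR1 by 0.65 (camera adjusted p = 9.95e-04, adjusted p = 0.31 with an estimated correlation). In the XTH family 5 of 15 rose and 1 fell, also when adjusted over the list alone, with XTH19 at 1.81, XTH20 at 1.66 and XTH17 at 1.48 (camera adjusted p = 0.049, 0.13 with the replicate block, 0.051 to 0.082 without either mock or either GA3 array, adjusted p = 0.48 with an estimated correlation). Expansins moved both ways, 4 up and 4 down of 15, or 4 and 5 when adjusted over the list alone, with EXPA8 at 1.23 and EXPA1 at 1.18 (camera adjusted p = 0.59). Of 10 BR-induced genes 3 rose, 5 when adjusted over the list alone, among them KCS1 at 1.16 and BAS1, a BR-inactivating enzyme, at 1.04 (camera adjusted p = 0.0045, adjusted p = 0.61 with an estimated correlation). Aquaporins rose in 3 of 10, 6 when adjusted over the list alone, with PIP2;7 at 1.00 and TIP1;2 at 0.60 (camera adjusted p = 0.0042, 0.055 without the EBR array of repeat 2, adjusted p = 0.50 with an estimated correlation). GA2OX7, a GA-inactivating oxidase, was at least 1.68-fold higher, and the list of such oxidases had 1 of 7 members higher, 4 when adjusted over the list alone (camera adjusted p = 0.045, 0.056 with the replicate block, 0.18 without the EBR array of repeat 1, 0.052 without the det2-1 against WT array of repeat 1, adjusted p = 0.48 with an estimated correlation). The ethylene synthesis gene ACO1 rose by 1.58, and ACS5 was at least 1.83-fold higher. GID1B rose by 0.75, SCL3 by 0.68, BZR1 by 0.58 and BIN2 by 0.49. PIF3 rose by 0.68 and PIF4 fell by 0.65, both light-signalling transcription factors.

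GA20OX2 stood at -0.07 (SE 0.36) with EBR, GA3OX1 at 0.51 (SE 0.30), and GA20OX1 at 0.15, and GA2OX1 was not above background with EBR, with 0 of 11 GA synthesis genes passing. Further large rises were BCA3 at 2.91, AT5G19890 at 2.32 (2.24 in a second probe) and RD20 at 2.25. The largest falls were AT4G11320 at -3.92, AT3G28550 at -3.55 (-0.42 in a dim second probe), AT4G15680 at -2.92, AT3G05950 at -2.85 and RHS13 at -2.82.

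The EBR count was 6279 with the replicate block, 1830 with scan day as a random block, 480 with plain background subtraction and 1475 with the deposited values, and median centring moved the share of higher genes from 48.6 to 65.2%. It was 1231 without the EBR array of repeat 1, 311 without either det2-1 against WT array and 272 without either GA3 array.

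Of the 1434 genes higher with PAC, 655 were lower with EBR, where independent lists give 76.3, and of the 861 lower with PAC 300 were higher with EBR, where independent lists give 43.2. The effects correlated at -0.56 across genes (Spearman -0.58). Both contain the PAC sample with opposite sign, and unchanged simulated arrays gave -0.71 with all noise in the samples and -0.33 with noise in the arrays. The covariance was -0.087 against a simulated -0.022, or -0.037 with the first experiment's own variance, so the overlap counts include noise of the shared PAC sample. Set against mock through the shared PAC sample, as the sum of the PAC and EBR effects, seedlings given PAC and EBR had 489 genes higher and 302 lower. EARLI1 was at 5.12 (SE 0.29), LTP3 at 3.67 and GH9B13 at 3.53, while AT4G11320 was at -5.60, AT3G19410 at -3.88 and PKT4 at -3.32. GA20OX2 remained at 2.17 (adjusted p = 0.038), CPD was at -1.44 and BR6OX2 at -1.51. The count was 2569 with the replicate block, 6358 with scan day as a random block, 0 with plain background subtraction, 429 with the deposited values and 271 with the experiment fitted alone. It was 147 and 523 without the mock array of repeat 1 or 2, and 271 without any single array of the second experiment.

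**Figure D1:**
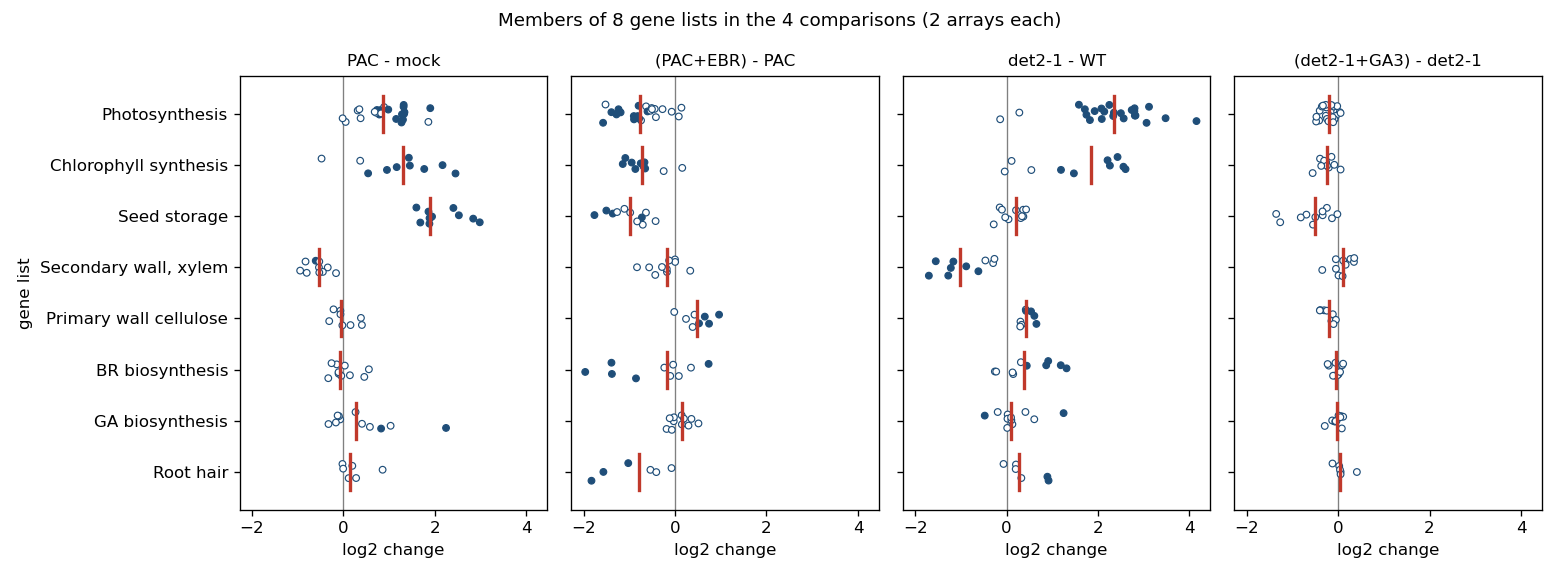
Log2 changes (x axis) of the members of 8 gene lists (y axis) in the 4 comparisons, as points, filled where the limma adjusted p was under 0.05, with red bars at the list medians. Photosynthesis medians were 0.85 with PAC, -0.76 with EBR, 2.34 in det2-1 and -0.19 with GA3.

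In det2-1 the probe for DET2 itself had a log2 change of -0.26 (SE 0.12, adjusted p = 0.21). The det2-1 allele is a point mutation, so this probe does not check the labels. Photosynthesis transcripts were much higher than in wild type, with LHCB1.3, a light-harvesting protein, at 4.15 (SE 0.46, adjusted p = 9.59e-04), RBCS1A of Rubisco at 3.48 (SE 0.21) and PSAK at 3.12 (SE 0.14). BR synthesis genes were higher, with BR6OX2 at 1.31 (SE 0.16, adjusted p = 0.0013), CPD at 1.19 (SE 0.10, adjusted p = 3.86e-04) and DWF4 at 0.87 (SE 0.21, adjusted p = 0.024). In all, 2654 genes were higher and 2498 lower, and the named changes had the same sign in 2 of 2 arrays.

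Photosynthesis genes rose in 22 of 24 members, 23 when adjusted over the list alone (median 2.34, camera adjusted p = 2.44e-23, adjusted p = 0.31 with an estimated correlation). Chlorophyll synthesis genes rose in 7 of 10, 8 when adjusted over the list alone, with CHLH at 2.60, GUN4 at 2.56 and PORB at 2.43 (camera adjusted p = 1.88e-07, adjusted p = 0.30 with an estimated correlation). Light signalling genes rose in 10 of 15, also 10 when adjusted over the list alone. PIF1 was at 1.85, PIF5 at 1.27 and PIF3 at 1.13 (camera adjusted p = 8.08e-06, adjusted p = 0.30 with an estimated correlation). Seed storage genes passed in 0 of 11, with a median of 0.21 (camera adjusted p = 0.68, 0.036 without the det2-1 against WT array of repeat 2). BR synthesis genes rose in 5 of 10, also 5 when adjusted over the list alone, with BR6OX1 at 0.91 (camera adjusted p = 0.018, adjusted p = 0.48 with an estimated correlation). KAO2 of GA synthesis rose by 1.25. GA20OX1 was at least 1.39-fold lower, and GA20OX2 stood at 0.61 (adjusted p = 0.21, 0.012 with the replicate block). GA3OX1 and GA2OX1 were not above background in det2-1 or WT. GA2OX2 had a log2 change of -0.75.

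Secondary wall and xylem genes fell in 7 of 10 members, 9 when adjusted over the list alone. XCP1 and XCP2, xylem proteases, were at -1.70 and -1.27 and the xylan synthesis gene IRX9 at -1.55 (camera adjusted p = 5.43e-06, adjusted p = 0.50 with an estimated correlation). Primary wall cellulose genes rose in 4 of 8, 7 when adjusted over the list alone, with CESA1 at 0.65, KOR1 at 0.61 and CSI1 at 0.54 (camera adjusted p = 0.0014, adjusted p = 0.31 with an estimated correlation). Expansins rose in 7 of 15 and fell in 2, 7 and 3 when adjusted over the list alone, with EXPA5 at 1.93, EXPA6 at 1.51 and EXPA4 at -1.45, and did not pass as a list (camera adjusted p = 0.079, 0.040 without the det2-1 against WT array of repeat 2). In the XTH family 4 rose and 4 fell, 5 and 5 when adjusted over the list alone, with XTH4 at 1.27 and XTH15 at 1.11, while XTH20 was at least 2.73-fold lower (camera adjusted p = 0.83).

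Auxin response genes fell in 8 of 20 and rose in 1, 9 and 3 when adjusted over the list alone, with IAA19 at -2.03 (-1.396 in its second probe), IAA29 at 1.44 and IAA6 at least 2.44-fold lower (camera adjusted p = 0.043, 0.087 with the replicate block, 0.42 without the det2-1 against WT array of repeat 2, adjusted p = 0.69 with an estimated correlation). Of 10 BR-induced genes 5 rose and 4 fell, 5 and 5 when adjusted over the list alone (camera adjusted p = 0.78). BEE2 was at 1.77, and BEE3 was 3.45-fold higher in the fit, with a WT signal not above background. Jasmonate genes fell in 5 of 10 and rose in 1, also when adjusted over the list alone, with VSP1 at least 2.87-fold lower, VSP2 at least 1.14-fold lower and JAZ1 at -0.73, and did not pass as a list (camera adjusted p = 0.21). Aquaporins rose in 4 of 10, also 4 when adjusted over the list alone, with PIP1;4 at 0.91 (0.06 in a dim second probe), TIP2;1 at 0.88 and PIP1B at 0.70 (camera adjusted p = 0.043, 0.47 without the det2-1 against WT array of repeat 1, adjusted p = 0.61 with an estimated correlation). Mitosis genes fell in 2 of 6, 4 when adjusted over the list alone, KNOLLE at -1.02 and CYCB1;2 at -0.37 (camera adjusted p = 0.039, 0.054 with the replicate block, 0.089 without the det2-1 against WT array of repeat 1, adjusted p = 0.48 with an estimated correlation). The root hair gene EXPA18 was higher at 0.92. PRP3 was 1.86-fold higher in the fit, with a WT signal not above background. The root hair list did not pass (camera adjusted p = 0.053, 0.040 with the replicate block). The DELLA gene GAI rose by 0.62 (0.85 in a second probe) and the GA receptor gene GID1B had a log2 change of -0.46. BKI1 rose by 0.49 and BIN2 by 0.38. CHI rose by 1.03, CHS was at least 1.82-fold and ACS11 at least 1.69-fold higher, ERS1 rose by 0.61 (0.54 and, for a dim one, -0.09 in further probes), and UBQ10 had a log2 change of -0.55.

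Other large rises were GAPB at 3.74 (0.09 in a dim second probe), AT5G22580 at 3.61 and AT4G19240. The last was 11.3-fold higher in the fit, with a WT signal not above background. The largest falls were BGAL7 at -3.65, AT4G07820 at -3.58, AT1G59900 of pyruvate dehydrogenase at -3.23, DR4 at -3.09 and AT4G11320 at -2.98. The det2 count was 8154 with the replicate block, 11116 with scan day as a random block and 7760 with the experiment fitted alone. It was 674 without the det2-1 against WT array of repeat 1 (66.3% higher against 51.5% here) and 470 without that of repeat 2.

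GA3 changed no gene past the threshold in det2-1. With limma 0 of 24063 genes passed, and 828 had an unadjusted p under 0.05, where chance gives 1203. With trend and robust eBayes 0 passed as well. CPD stood at -0.20 (SE 0.10), BR6OX2 at -0.23 (SE 0.16), DWF4 at -0.07 (SE 0.21), GA20OX2 at -0.29 (SE 0.29), GA3OX1 at -0.05 and DET2 at 0.09, and GA20OX1 and GA2OX1 were not above background in either group. As lists, seed storage had a median of -0.50 (camera adjusted p = 4.97e-08, adjusted p = 0.50 with an estimated correlation) and 5 of 11 members lower when adjusted over the list alone, but only 2 of 11 were above background with GA3. Photosynthesis had -0.19 (camera adjusted p = 2.34e-06, adjusted p = 0.53 with an estimated correlation), with array medians of -0.33 and -0.02. Chlorophyll synthesis had -0.25 (camera adjusted p = 2.59e-05, adjusted p = 0.30 with an estimated correlation) and primary wall cellulose -0.20 (camera adjusted p = 1.15e-04, adjusted p = 0.31 with an estimated correlation). GA 2-oxidases, 3 of 7 above background with GA3, had 0.19 (camera adjusted p = 0.024, adjusted p = 0.48 with an estimated correlation) and expansins 0.08 (camera adjusted p = 0.042, adjusted p = 0.62 with an estimated correlation). Without the GA3 array of repeat 1 the photosynthesis median turned to 0.0606 (adjusted p = 0.61), and the calls of chlorophyll synthesis (0.22), primary wall cellulose (0.075), GA 2-oxidases (0.060) and expansins (0.61) were lost. Without that of repeat 2 the calls of seed storage (0.24) and GA 2-oxidases (0.33) were lost.

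Scan day as a random block called 4726 GA3 genes and the experiment fitted alone 1, while the other fits, the replicate block included, called 0. In simulated arrays with all noise in the samples 73.3% of the GA3 calls of the scan-day block were false, and both GA3 arrays and a det2-1 against WT array were scanned on the same day.

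Set against wild type, det2-1 with GA3 had 998 genes higher and 817 lower. LHCB1.3 was at 3.74 (SE 0.65) and AT5G22580 at 3.29, while AT1G59900 was at -3.20. AT4G19240 was also higher but not above background in WT, and BGAL7 and AT4G07820 were lower and not above background with GA3. BR6OX2 was at 1.08 (adjusted p = 0.029) and CPD at 0.98 (adjusted p = 0.010). The det2 and GA3 effects correlated at -0.34 across genes (-0.14 without the GA3 array of repeat 1), against -0.50 in unchanged simulated arrays with all noise in the samples, and their covariance was -0.021 against -0.0089. The count was 4478 with the replicate block, 9814 with scan day as a random block and 3977 with the experiment fitted alone. It was 109 without either array of repeat 1 (75.2% higher against 55.0% here) and 51 without either array of repeat 2 of the second experiment (66.7%).

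**Figure D2:**
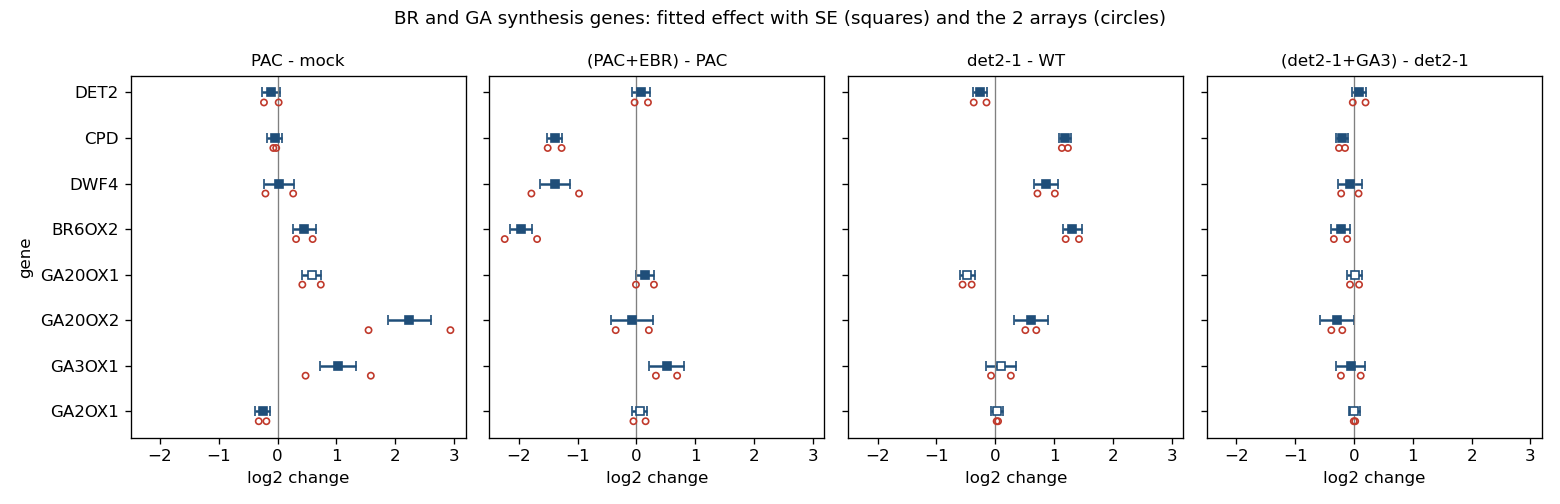
Log2 change (x axis) of 8 BR and GA synthesis genes (y axis) in the 4 comparisons, as the fitted effect with its SE (squares) and the 2 dye-corrected arrays (circles), with open squares where a group was not above background. CPD was at -1.39 with EBR and 1.19 in det2-1, and GA20OX2 at 2.24 with PAC.

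PAC treatment and the det2-1 mutation shared part of their changes. No PAC sample was given GA, so these values do not tell whether GA depletion caused the PAC changes. PAC and det2 effects came from separate samples, apart from the dye effect that the fit takes from the second experiment. They correlated at 0.48 across genes (Spearman 0.37), against 8.32e-04 in unchanged simulated arrays. With no dye effect in the fit the correlation was 0.46. Of 1434 genes higher with PAC, 800 were higher in det2-1, where independent lists give 158, and of 861 lower 452 were lower, where independent lists give 89.4. The effects differed for 945 genes. CPD differed by -1.23 (SE 0.16, adjusted p = 0.016), AT5G22580 by -3.35 and AT1G52060 by -3.15. HSD1, AT1G52100, AT1G68250 and AT4G19240 also passed, as did GA20OX1, but the first 3 were not above background in det2-1, AT4G19240 in PAC, mock or WT and GA20OX1 in PAC, mock or det2-1 on the arrays against mock and WT, so no size is given. The count of differing genes was 4511 with the replicate block, 2598 with scan day as a random block, 34 with plain background subtraction (76.5% higher against 54.2% here) and 553 with median centring. It was 140, 394 and 1503 without the mock array of repeat 1, that of repeat 2 or either EBR array, 0 without the det2-1 against WT array of repeat 2 and 48 without any other array of the second experiment.

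EBR and GA3 effects correlated at -0.12 across genes (0.0596 and -0.21 without the GA3 array of repeat 1 or 2) and differed for 1007 genes. EARLI1 was higher for EBR by 4.25 (SE 0.33), LTP3 by 4.04 and BCA3 by 3.29. AT4G11320 differed by -4.86, AT3G28550 by -3.44, CYP81F4 by -3.13, BR6OX2 by -1.74 (adjusted p = 0.021) and CPD by -1.19 (adjusted p = 0.020). The count was 4637 with the replicate block, 2401 with scan day as a random block, 0 with plain background subtraction and 511 with the deposited values. It was 588 without the EBR array of repeat 1 and 0 without any single array of the second experiment, and the share of higher genes moved from 53.7 to 65.6% with median centring.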

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

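All tests of explanations in this part were chosen after the results were seen. Control spots that the comparisons do not use carried signal above the randomized negative controls. In each set 128 values (8 spots, 8 arrays, 2 dyes) were set against the 95th percentile of those negatives. At the highest amount listed, 128 values of LHCB1.3 were brighter, 128 of AT4G00810, 127 of PMH1, 118 of AT5G57480, 113 of AT3G44150 and 110 of AGP11. The LHCB1.3 control spots had log2 changes of 1.75 with PAC, -1.63 with EBR and -0.43 with GA3, beside 1.86, -1.52 and -0.41 for the gene's own probe. At the listed amount of 10 they were 0.82, -0.89 and -0.22. The other control genes had smaller changes. With PAC, spots and probe differed in sign for AT3G44150, at -0.12 and 0.13, and had the same sign for the others.

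The seed storage rise with PAC was set against 15 further seed genes. RNA of seeds, or of embryos arrested before germination, is a candidate explanation. It asks that these genes rise too, and their median log2 change was 1.60, with 8 of 15 rising, among them OLEO4 at 2.79 and CLO1 at 2.54, but TIP3;2 at 0.05. Dye bias as the whole cause would cancel in PAC+EBR against mock, where the seed storage median was 1.197. An effect of PAC on these genes within germinated seedlings was not tested apart from arrested seeds and stays open.

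PAC and EBR effects oppose each other. A shared PAC extract and fitted dye term as the whole cause asks for a covariance no larger in size than the simulated -0.037, and the observed value was -0.087. The fit takes the dye bias to be equal in both experiments. A dye bias of the first experiment alone would enter the PAC and EBR effects with opposite sign, so this test cannot exclude it. PAC and EBR arrays of different repeats, which share no PAC sample, still correlated at -0.37 and -0.41, though they share dye orientation. A share of the opposition may still come from the extract or from dye bias, and an EBR effect opposite to that of PAC stays open.

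The absence of GA3 calls was weighed against low power and a deviating det2-1 extract. In a single simulated draw with noise independent between arrays, GA3 changes of log2 size 1 were recovered in 100% of cases. This argues against too few arrays to call changes of that size. Of size 0.5, 37.0% were recovered, and 17.6% in the det2 comparison, so smaller changes could be missed. The det2 effect, also on 2 arrays in the same fit, had 5152 calls. Its changes were larger, with a median absolute log2 change of 0.159 against 0.0775 for GA3. That count therefore does not tell whether small GA3 changes could be called. If the arrays of a repeat share a det2-1 extract, as the labels imply, a deviating extract asks for lower correlations of det2 and GA3 arrays within repeats than between them. Over all genes they were -0.46 and -0.32 within and 0.10 and -0.05 between, and over brighter genes -0.467 and -0.281 within and -0.069 and -0.277 between, in that direction in both. The arrays of a repeat also share dye orientation, which gives the same order, so by this order a deviating extract and dye bias cannot be told apart, but dye bias cancels in the GA3 effect, and a small GA3 effect stays open.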

How the results depend on the processing

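The replicate block was set in the first experiment only, so counts of the second experiment changed through the shared spread alone. With the replicate block, where same-numbered arrays share a sample, 6229 genes passed for the PAC effect, 6279 for the EBR effect, 8154 for the det2 effect, 2569 for PAC+EBR against mock, 4478 for det2-1 with GA3 against WT, 4511 for PAC minus det2 and 4637 for EBR minus GA3. With scan day as a random block the PAC effect had 1627, the EBR effect 1830, the det2 effect 11116, the GA3 effect 4726, PAC+EBR against mock 6358, det2-1 with GA3 against WT 9814, PAC minus det2 2598 and EBR minus GA3 2401. In simulated arrays with all noise in shared samples, the replicate block gave more false calls than the chosen design for each effect, and the scan-day block gave more for det2 and GA3 but fewer for PAC (7.89%) and EBR (7.15%). Each experiment fitted alone gave 271 for PAC+EBR against mock, 7760 for det2, 1 for GA3 and 3977 for det2-1 with GA3 against WT, and has no fit for the differences between experiments. Plain background subtraction, over 17335 genes, gave 117 for PAC (88.0% higher against 62.5%), 480 for EBR, 0 for PAC+EBR against mock, 34 for PAC minus det2 (76.5% higher against 54.2%) and 0 for EBR minus GA3. Median centring gave 553 for PAC minus det2. It moved the share of higher genes from 48.6 to 65.2% for EBR and from 53.7 to 65.6% for EBR minus GA3, and for PAC to 52.7%. The deposited values, over 10901 genes, gave 1466 for PAC, 1475 for EBR, 429 for PAC+EBR against mock and 511 for EBR minus GA3, with shares of higher genes of 47.5% against 62.5% for PAC and 49.0% against 61.8% for PAC+EBR against mock. An absolute log2 change of at least 1 left 571 for PAC (80.2% higher), 595 for EBR, 1140 for det2, 492 for PAC+EBR against mock, 895 for det2-1 with GA3 against WT, 592 for PAC minus det2 and 559 for EBR minus GA3. Of 88 list tests 30 passed with camera, 0 with its estimated correlation and 14 with fry. Of the 68 tests possible with the deposited values or with not-found spots left out, which hold 25 of the 30 calls, 14 and 17 passed, the latter fit chosen after the data were seen. Leaving out 1 array at a time, with the lone array of that comparison assumed to vary like the others, gave 124 to 3047 for PAC, 272 to 2381 for EBR, 470 to 5817 for det2, 0 to 0 for GA3, 147 to 753 for PAC+EBR against mock, 51 to 2278 for det2-1 with GA3 against WT, 0 to 1503 for PAC minus det2, 0 to 927 for EBR minus GA3 and 26 to 34 list calls. Correlations ran from 0.42 to 0.51 for PAC and det2, -0.21 to 0.0596 for EBR and GA3, -0.57 to -0.48 for PAC and EBR and -0.34 to -0.14 for det2 and GA3. The value 0.0596 turns the sign of the EBR and GA3 correlation and arose without the GA3 array of repeat 1. Without that array the GA3 list medians also turned for auxin response, to -0.144 (adjusted p = 0.018, while without the GA3 array of repeat 2 that list passed at a median of 0.167 with adjusted p = 0.0043), and for photosynthesis, to 0.0606 (adjusted p = 0.61), and the cause was not tested. No passing named gene turned direction. Over all settings the call status of named genes, passing or not, was the same in 3509 cases, lost in 686 and gained in 16. For list shifts the counts were 1703, 78 and 25. The losses of named genes were uneven. With plain background subtraction 77 calls were lost and 106 cases were the same, and many were also lost without an array of the second experiment. In the latter fits the spread comes from the first experiment alone, so such losses do not show that a result hangs on the array left out. Spots with 38.3 to 49.9% not found per array limit what can be said of dim genes. Sign changes of genes passing in neither fit were counted as unchanged.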

Other observations

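Gene families were formed after the data were seen, from the letters that start a RefSeq symbol, and 211 families with at least 8 measured genes were tested with camera in 4 comparisons. In 844 tests 46 passed at the preset correlation and the adjusted p was 0.93 in the best of them with an estimated correlation. As for the lists, the estimated variant rests on few degrees of freedom, so this loss does not by itself show correlation between genes. The PTAC family of plastid transcription proteins rose in 6 of 12 members with PAC, fell in 4 with EBR and rose in 9 in det2-1. The genes with HCF symbols, grouped by these letters only, rose in 6 of 12, fell in 5 and rose in 8. The GPAT acyltransferases fell in 4 of 9 with PAC (median -0.54) and rose in 3 with EBR (0.58), where 6 of 20 KCS and 4 of 8 LACS genes of fatty acid elongation and activation also rose.

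In det2-1 the GSTU glutathione transferases fell in 13 of 25 members and rose in 3 (median -0.47), the NAC transcription factors fell in 23 of 77 and rose in 3, and the WRKY transcription factors fell in 11 of 61 and rose in 0. Over all 24063 genes 2498 fell and 2654 rose in det2-1.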
